A study of Danio rerio with 32 samples.

How the data were processed

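RNA from whole zebrafish larvae was measured on 32 one-colour Cy3 Agilent arrays of design 036575. Per the labels, larvae were held for 96 h in beakers of 8 fish, each extract pooled 4 fish and 600 ng of total RNA was labelled, and the UV-treated stock had been irradiated for 4 h. The spot intensities were extracted by the authors with Agilent Feature Extraction 10.7.3.1 under the protocol GE1_107_Sep09, per the file headers, and the deposited scanner files give them as background-subtracted and spatially detrended signals. The deposited series values are log2 values centred on each probe's median over the arrays. Its scale, centring and direction were found by comparison with the scanner values, and the columns correlated with them at 1, with column medians from -0.131 to 0.107. The other columns used, the flags for saturation, outlier spots and signal well above background, are as deposited by the scanner software per the file headers. How fish were assigned to beakers, and whether extracts came from separate clutches or days, is not given in the sources used here.

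Each array held 62976 spots, of which 61657 were not controls, and spots of 1 probe were averaged to 43603 probes. Outlier spots were left out, which left 124 missing probe values, and 0 spots were saturated. Values were log2 of the processed signal minus the array's 75th percentile. A probe was tested if it was well above background on at least 3 arrays of at least 1 group. This kept 34698 probes, of which 93 were left out for a missing value, so that 34605 were tested, for 20558 genes. Names were updated through a RefSeq list of genes of the assembly GRCz12tu, used for names only. By accession 25724 probes were named, by symbol or synonym 5459, and 12420 kept the name in the file. Positions are those of the files, on danRer7 (Zv9).

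All 8 groups were fitted together with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table, and tests were two-sided, moderated by the empirical Bayes step (prior df 3.52, residual df 24) and adjusted by the Benjamini-Hochberg method over all tested probes. Probes with an adjusted p under 0.05 are called. The comparisons were each exposed group against the control of its series, the difference of the effects of both forms at each concentration, the interaction, the averaged effects of form and concentration, and control against control. An exact test of 3 against 3 arrays cannot go below 0.1. These comparisons, 30 gene lists, the rule for named genes and most alternatives were set before the data were examined. Named genes had a symbol and an adjusted p under 0.05, and for effects of exposure no overlap between exposed and control arrays. With 1 probe per gene, the 12 largest changes each way were named at 90.4 mg/L and 5 each way elsewhere. Where under 5 passed, the smallest p-values up to 5 are given as values. Up to 4 members of a described list were also named. A fold against a group with no array above background was computed with that group set to the lowest signal called well above background on each of its arrays, or to its own value where higher, and is written "at least". Where such a group enters a difference of effects or an averaged effect, the adjusted p is given without a size. The same holds for mcoln1a and gh1, most of whose exposed arrays were not above background either.

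Lists were tested with camera at its preset correlation of 0.01, on 1 probe per gene, and again with an estimated correlation. For the averaged effects and the interaction, the called members of a list were compared with all genes by Fisher's exact test, one-sided. That test takes genes as independent, while genes of a list can move together on an array, so its p-values can be too small. A list is described where camera called it and at least 1 member passed, or where at least 3 members passed, in an effect of exposure, a difference between the forms or the averaged effect of form. For the interaction and the averaged effect of concentration, lists with at least 3 called members are given with their counts. This rule was chosen after the list results were seen, and the lists it leaves out are given as ranges among the other observations. The clock genes bmal1a, dbpa, per1b and nr1d2b in the averaged effect of form, and the control levels of lmbr1l, were chosen after their values were seen.

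Alternatives changed 1 choice at a time: normexp background correction, quantile normalization, no filter or a filter on all 32 arrays, array weights, the slide as a fixed or random block, the array row as a covariate, pooled controls, the compared groups alone, the deposited value table, a threshold of 0.1 or 1.5-fold, a block on the replicate number, and each array left out. Added after the data were seen were leaving out the 3 arrays with a median CV above 20%, leaving out the 2 arrays at the end of principal component 1, the median CV as a covariate, and leaving out slide 2. The arrays lay on 4 slides of 8, each scanned at once, so that slide and scan cannot be separated. Values within a slide for called probes or named genes come from arrays that chose them. They show sizes only and are no separate test of the slide.

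The fit was tested on simulated data of 34605 probes with 200 changed. Each probe was drawn independently, without the variation that probes of an array share, so the rates below need not hold for the real arrays. For UV-treated 90.4 mg/L it called 3%, 34.3% and 83.3% of changes of 0.5, 1 and 2 on the log2 scale, with 2 false calls. For parent 45.6 mg/L it called 6%, 43.3% and 81.8%, with 4 false calls, and for the difference at 90.4 mg/L 0%, 13.4% and 57.6%, with 4 false calls. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.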

Results

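Whole zebrafish larvae were profiled after 96 h in water holding nitroguanidine, an energetic component of insensitive munitions. The compound was given either as the parent form or as a stock that had been irradiated for 4 h with ultraviolet light in a photo-reactor, here called the UV-treated form. The array titles, treatment labels and series description name nitroguanidine for both series, while 1 phrase of the treatment protocol calls the irradiated material IMX-101, a mixture with other components. That conflict is not settled by the sources used here, and the values below follow the titles. Larvae of each series were held at measured concentrations of 90.4, 45.6 or 5.5 mg/L or at 0 mg/L, and each 0 mg/L group is called the control of its series. The labels speak of 6 replicate control exposures where the series holds 3 control arrays per form, and they do not say whether both control groups were a single experiment, so each form was compared with its own. The 32 arrays comprised 3 parent controls and 4 arrays at each parent concentration. The UV-treated series had 3 controls, 5 arrays at 5.5 mg/L, 5 at 45.6 mg/L and 4 at 90.4 mg/L. Each extract pooled 4 larvae. The labels do not say whether extracts of a group came from separate clutches or days, so the p-values measure only the spread between these extracts. The 75th percentile of the processed signal ranged from 292.2 to 693 over the arrays, and 68.7% to 83.9% of probes were well above background on an array. The number of arrays limits the precision of every value. The series asked how the transcript response to the parent compound differed from that to the UV-treated form, and its title names oxidative stress as the effect of interest.

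The numbers of responding transcripts differed widely between the forms and concentrations. Of 34605 probes tested, 2662 passed an adjusted p of 0.05 in the UV-treated 90.4 mg/L larvae against their control, of which 405 were higher and 2257 lower. The parent form gave 302 probes at 5.5 mg/L (266 higher, 36 lower), 136 at 45.6 mg/L (132 higher, 4 lower) and 11 at 90.4 mg/L (9 higher, 2 lower). The UV-treated form gave 3 probes at 5.5 mg/L and 6 at 45.6 mg/L. Between the UV-treated control and the parent control limma called 0 probes, with 2233 at an unadjusted p under 0.05. That count was 313 when limma weighted the arrays by quality, 232 without parent control replicate 3 and 1 without UV-treated control replicate 2.

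**Figure D1:**
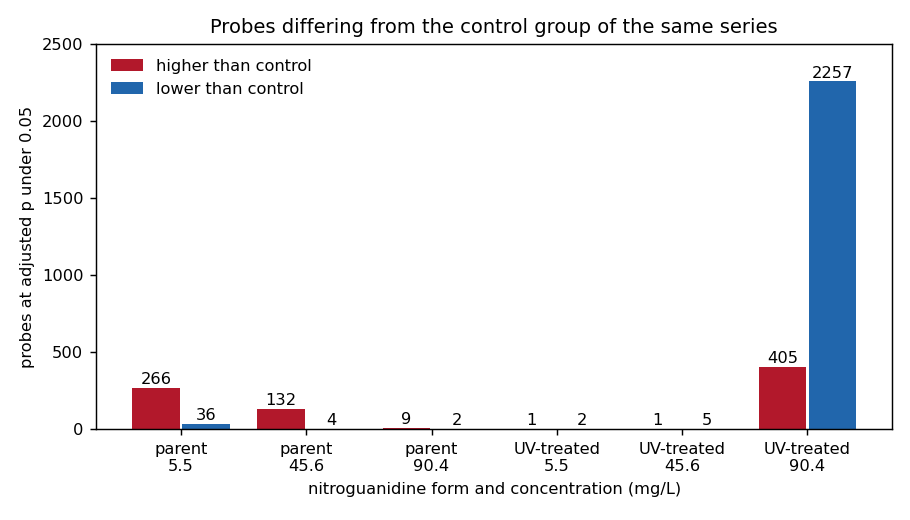
Number of probes at an adjusted p under 0.05 (vertical axis) for each form and concentration of nitroguanidine in mg/L (horizontal axis), each against the control of its own series, with red bars for probes higher and blue bars for probes lower than control. The bars of the UV-treated 90.4 mg/L larvae stand at 405 and 2257 probes.

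Larvae exposed to 5.5 mg/L of the parent compound had lower transcript levels of a few glucocorticoid-responsive and clock genes, 2 of 29 and 4 of 38 measured, and neither list held as a group with an estimated correlation. The glucocorticoid receptor co-chaperone fkbp5 fell by 3.74 on the log2 scale (SE 0.72, adjusted p = 0.0215, 4 exposed against 3 control arrays) and the glucocorticoid-induced transcription factor klf9 fell by 3.50 (SE 0.64, adjusted p = 0.0184). The nuclear receptor gene rorcb fell by 1.71, the clock output repressor nfil3-5 fell by 1.34 and the core clock activator bmal1a fell by 0.67 (SE 0.12, adjusted p = 0.0184). The cryptochrome cry4 fell by 0.88. The immediate-early gene egr2a fell by 1.97 and the cell cycle inhibitor cdkn1d fell by 1.61. Among the genes that rose were lmbr1l (log2 change 4.48, SE 0.96), the melatonin receptor mtnr1ba (at least 3.89-fold) and the potassium channel kcnq3 (at least 3.85-fold). Others were the cell polarity gene llgl1 (at least 3.08-fold) and the lysosomal channel mcoln1a (adjusted p = 0.048). The size for mcoln1a is not given, since it was above background on only 1 of 4 exposed arrays. The lmbr1l probe also differed between the control groups, at a mean log2 level of -5.68 (SD 0.68, n = 3) in the parent control and -1.55 (SD 1.29, n = 3) in the UV-treated control. It is a single probe, and whether a variant between strains or clutches rather than exposure set its level was not tested, for this and the other comparisons naming it. Over the alternatives the log2 change of lmbr1l at parent 5.5 mg/L ranged from 1.921 to 4.847.

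By gene group, 2 of 29 measured genes of the glucocorticoid and stress axis fell at parent 5.5 mg/L, and 3 fell when adjusted over the list alone (median log2 change -0.40). The list test called the group at adjusted p = 9.51e-05, and the call was lost at adjusted p = 0.922 with an estimated correlation. Of 38 circadian clock genes, 4 fell, while 5 fell and 1 rose when adjusted over the list alone. The median of the clock list was 0.08 and its mean -0.03, and the list test did not call it (adjusted p = 0.569; adjusted p = 0.992 with an estimated correlation). Of 77 oxidative phosphorylation genes 1 rose, ndufa1 (0.84), which encodes a complex I subunit, although the list median was -0.10. The call of that list was lost with the slide as a fixed block (adjusted p = 0.0387 without it; adjusted p = 0.982 with an estimated correlation). Of 56 neuronal genes none passed over all probes and 7 were higher when adjusted over the list alone (median log2 change 0.42, adjusted p = 2.25e-07; adjusted p = 0.83 with an estimated correlation). The medians of other tissue lists were also above 0, 0.50 for liver, 0.46 for extracellular matrix and 0.26 for intestine, with no member passing.

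The parent 5.5 mg/L counts rested on few arrays. Leaving out exposed replicates 1, 2, 3 or 4 gave 104, 22, 17 or 11 probes, and leaving out control replicates 1, 2 or 3 gave 7, 0 or 641 (limma, 5057 at an unadjusted p under 0.05 in the reported fit). Of the 14 named genes 0 kept the call in all of these fits. Of the 4 exposed arrays 3 lay on slide 2, which held no control. With the slide as a fixed block 12 probes were called (7 higher, 5 lower), all shared with the 302. Within slide 4, the slide with both groups (1 array of each), the median log2 change was 0.69 for the probes called higher and -1.15 for those called lower. The list medians within slide 4 were -0.29 for the glucocorticoid axis, 0.03 for the clock and 0.36 for the neuronal genes. With the controls of both series pooled the count was 23 (10 higher, 13 lower).

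At 45.6 mg/L of the parent compound, larvae showed a strong rise of interferon-stimulated genes. The antiviral GTPases mxb and mxe rose at least 99.6-fold (SE 0.88 log2, adjusted p = 3.12e-05) and at least 46-fold (SE 0.60, adjusted p = 1.3e-06), and the ubiquitin-like modifier isg15 rose 42.7-fold, from a mean log2 level of -2.30 (SD 1.26, n = 3) to 3.12 (SD 0.59, n = 4). The antiviral gene ifit8 rose at least 39.9-fold and ifi27.2 rose 34.1-fold, the latter with 3 other probes of the gene called in the same direction. Of 35 measured interferon response genes 15 rose and none fell, and 20 rose when adjusted over the list alone. The list's median log2 change was 1.33 and its mean 1.89. The list test called it at adjusted p = 9.65e-50 and it kept the call at adjusted p = 6.28e-06 with an estimated correlation. The mxb probe lies on chromosome 1 between 6861698 and 6861841, the mxe probe on chromosome 9 between 33865929 and 33865988 and the isg15 probe on chromosome 5 between 21896031 and 21896090 of the danRer7 (Zv9) assembly.

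**Figure D2:**
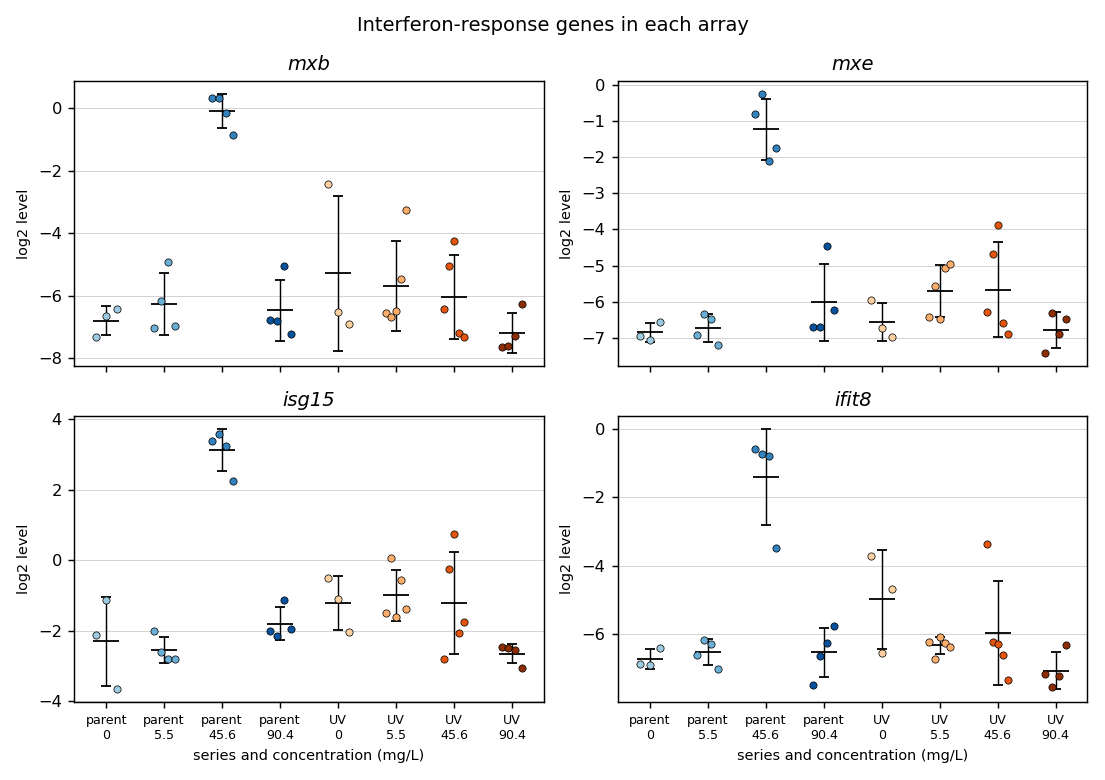
Normalized log2 level (vertical axis) of mxb, mxe, isg15 and ifit8 in each of the 32 arrays by series and concentration in mg/L (horizontal axis), with a point per array and horizontal and vertical bars for the group mean and SD. In parent 45.6 mg/L larvae isg15 had a mean of 3.12 (SD 0.59), against -2.30 (SD 1.26) in the parent control.

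Among the genes that fell at parent 45.6 mg/L, rorcb fell by 1.68 (SE 0.32, adjusted p = 0.00519) and the muscle actin-binding protein xirp2a fell by 0.62 (SE 0.14, adjusted p = 0.0395). Markers of myeloid and lymphoid cells had a median log2 change of 0.32 in the same larvae, and none of the 43 passed over all probes (1 when adjusted over the list alone; adjusted p = 0.922 with an estimated correlation). With the slide as a fixed block 132 probes were called, 127 of them shared with the 136. Within slides 1, 3 and 4, with 1 exposed and 1 control array each, the median log2 change of the probes called higher was 2.95, 2.32 and 2.50, and that of the interferon list 1.66, 0.63 and 1.87. The calls of mxb, mxe, isg15, ifit8 and ifi27.2 held without any 1 of the arrays, whereas rorcb had an adjusted p of 0.103 without control replicate 1 and 0.0625 without control replicate 3. The call of xirp2a was lost in 15 of 25 alternatives (highest adjusted p 0.999). With the compared groups fitted alone 69 probes were called, and 73 with probes above background on all 32 arrays.

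At 90.4 mg/L of the parent compound few transcripts differed. The phosphoinositide phosphatase inpp4aa rose 2.76-fold (log2 change 1.47, SE 0.27, adjusted p = 0.0376) and aep1 rose 2.38-fold (log2 change 1.25, SE 0.24, adjusted p = 0.0456). Next by p-value came the phospholipid flippase atp8a1 with a log2 change of 1.09 (adjusted p = 0.0904), the transcriptional coregulator eya3 with -1.32 (adjusted p = 0.097, its other 2 probes with the opposite sign) and runx1t1 at 2.46-fold higher (adjusted p = 0.125). These 3 genes did not pass. The 11 probes became 2, 1, 0 or 0 without exposed replicates 1, 2, 3 or 4 and 0, 0 or 106 without control replicates 1, 2 or 3. With the slide as a fixed block and with normexp background correction limma called 0 probes (3009 at an unadjusted p under 0.05 in the reported fit). Quantile normalization gave 10 higher and 4 lower. Within slides 1 and 3 the 5 named genes had the sign of the change over all arrays, and the median log2 change of the probes called higher was 1.74 and 2.03. The same arrays chose these genes and probes, so these values are no separate test of the slide. For inpp4aa and aep1 the rule of no overlap fixed the sign.

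The UV-treated form at 5.5 mg/L gave 3 called probes. Array weights gave 180 (63 higher, 117 lower) and pooled controls of both series 47 (15 higher, 32 lower). The nuclear receptor nr1d2b, a repressor within the clock loop, fell by 0.92 on the log2 scale (SE 0.16, adjusted p = 0.0406, 5 exposed against 3 control arrays) and the lipid receptor gene gpr55a fell by 1.48 (SE 0.26, adjusted p = 0.0406). The clock activator bmal1a had a log2 change of 0.62 (SE 0.12, adjusted p = 0.0753) and the splicing factor plrg1 0.63 (adjusted p = 0.0753, 1 of its other 3 probes with the opposite sign). The growth hormone gene gh1 was higher (adjusted p = 0.0824), without a size because it was above background on 2 of 5 exposed and 0 of 3 control arrays. The genes bmal1a, plrg1 and gh1 did not pass. Of 38 clock genes 1 fell over all probes, and 7 rose and 10 fell when adjusted over the list alone (median log2 change -0.29, adjusted p = 0.0446; adjusted p = 0.982 with an estimated correlation). The list call was also lost with the slide as a fixed block. In 52 phototransduction genes none passed over all probes and 2 were lower when adjusted over the list alone (median -0.24; adjusted p = 0.922 with an estimated correlation). The count of 3 probes (1 higher, 2 lower) became 0, 1 or 0 without control replicates 1, 2 or 3 and 0, 11, 0, 0 or 0 without exposed replicates 1 to 5. It was 0 with the slide as a fixed block (2079 at an unadjusted p under 0.05 in the reported limma fit) and 1 (0 higher, 1 lower) after quantile normalization. Within slides 1 and 3 the clock list medians were 0.05 and -0.31.

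At 45.6 mg/L of the UV-treated form the organic anion transporter slc22a6l rose 3.19-fold (log2 change 1.67, SE 0.29, adjusted p = 0.025, 5 against 3 arrays). That call was lost in 11 of 26 alternatives, among them leaving out any 1 of the controls or exposed replicate 2, 3 or 5 (highest adjusted p 0.284 over all alternatives). The mitophagy receptor fundc1 had a log2 change of 1.02 (adjusted p = 0.0562), the protocadherin pcdh2g4 -1.23 (adjusted p = 0.0661), the co-chaperone dnajb2 -1.02 (adjusted p = 0.0696, its other probe with the opposite sign) and plrg1 0.58 (adjusted p = 0.0759), and these did not pass. In the glucocorticoid and stress axis list none of 29 genes passed over all probes, and 4 were higher when adjusted over the list alone (median 0.44, adjusted p = 2.46e-06; adjusted p = 0.83 with an estimated correlation). Replicate 3 stood highest in that list, at a level of 0.892 (others 0.097 to 0.605), and lay at the end of principal component 1. The 6 probes (1 higher, 5 lower) became 1 or 2 without control replicates 1 or 3 and 245, 0, 130 or 3 without exposed replicates 1, 3, 4 or 5. Array weights gave 1385 probes and pooled controls 26. Quantile normalization gave 2 higher and 5 lower, the slide as a fixed block gave 16 probes, and within slide 1 the median log2 changes were 1.17 and -2.15 for the probes called higher and lower.

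Larvae in 90.4 mg/L of the UV-treated form had the largest number of changed transcripts, 405 probes higher and 2257 lower. Of 33 measured genes of xenobiotic metabolism and the aryl hydrocarbon receptor 0 passed (limma). The cytochrome P450 gene cyp2k22 rose 9.84-fold (log2 change 3.30, SE 0.93, adjusted p = 0.026, 4 against 3 arrays, 1 control array above background), the glutathione transferase gstp1.1 rose 9.38-fold (3.23, SE 0.79, adjusted p = 0.0103) and the peroxiredoxin prdx1 rose 3.54-fold (1.83, SE 0.41, adjusted p = 0.00492). The transporter slc22a6l rose 5.62-fold (2.49, SE 0.31, adjusted p = 6.03e-05). The intestinal apolipoprotein apoa4a rose 5.83-fold, the erythrocyte anion exchanger slc4a1a 5.34-fold (2.42, SE 0.59, adjusted p = 0.00997) and the urate transporter slc2a9l1 at least 4.23-fold. The iron-sulfur protein gene rfesd rose 5.12-fold, the acute-phase gene crp2 4.16-fold, the epithelial calcium channel trpv6 3.71-fold, the ribonucleoprotein snu13a 3.69-fold and the dynein assembly factor dnaaf6 at least 3.42-fold.

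Among the genes that fell at UV-treated 90.4 mg/L, lmbr1l fell by 4.62 on the log2 scale, the sex-determination factor dmrt1 fell by 3.35, the bloodthirsty-related gene btr32 fell by 2.43 and the actin nucleator spire2 fell by 2.38. Over the alternatives the change ranged from -5.441 to -1.84 for lmbr1l and from -4.323 to -1.387 for dmrt1, so their sizes are uncertain. The transcription factor bcl11ba fell by 2.37 (SE 0.33, adjusted p = 0.000141) and the endodermal factor sox32 fell at least 5.07-fold. The synaptic scaffold magi2a fell at least 5.24-fold, the kinase gene pimr128 fell by 2.34 (its other probe with the opposite sign) and the phosphatase ppef1 fell by 2.25. The glucuronosyltransferase ugt1b7 fell by 2.23 (SE 0.26, adjusted p = 5.44e-05), csmd1a fell 4.61-fold and the protocadherin pcdh9 fell 4.59-fold. The slc22a6l probe lies on chromosome 21 between 27887872 and 27887931, the bcl11ba probe on chromosome 17 between 17965747 and 17965806 and the ugt1b7 probe on chromosome 11 between 31172641 and 31172700 of danRer7. The calls of slc22a6l, btr32, bcl11ba, ppef1, ugt1b7 and csmd1a held without any 1 of the arrays and in every other alternative tried. Of the 50 named genes called there 15 held in all of these, and 19 without any 1 array. Among those that did not, ndufa9a lost its call in 16 of 25 alternatives, dnaaf6 in 13 of 24, ifnphi1 in 13 of 25, cahz in 10 of 25, crp2 in 9 of 25 and pimr128 in 8 of 24. The call of prdx1 was lost without UV-treated control replicate 3 (adjusted p = 0.0656), as was that of slc4a1a (adjusted p = 0.0715). The gene gstp1.1 lost its call without control replicate 2 (0.0641), control replicate 3 (0.0557) or exposed replicate 2 (0.0579).

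By gene, 1666 of 20558 were called at UV-treated 90.4 mg/L, 212 higher and 1454 lower. Of the lists below, those of glucose, fatty acids, inflammation and the clock and the smaller groups had no larger share called than all genes. The antioxidant and interferon lists had about the same share. Of 34 measured erythrocyte and haem genes 9 rose and none fell at UV-treated 90.4 mg/L, and 14 rose when adjusted over the list alone. Beside slc4a1a, the erythrocyte carbonic anhydrase cahz rose by 1.48 on the log2 scale, as did the haem synthesis enzymes hmbsb by 1.41 (SE 0.30, adjusted p = 0.00308) and cpox by 1.24. The list's median log2 change was 0.81 (adjusted p = 3.49e-10), and the call was lost at adjusted p = 0.814 with an estimated correlation. The mean log2 difference of the list from its mean over all arrays varied widely, at -0.071, 0.462, 1.453 and 0.309 on the exposed arrays. It was -0.559 to -0.137 on the controls. Single arrays of other groups reached 1.035 (parent 45.6 mg/L replicate 4) and 1.02 (UV-treated 45.6 mg/L replicate 5). Of 45 antioxidant and glutathione genes 3 rose (gstp1.1, prdx1 and the thioredoxin reductase txnrd3, 0.86, SE 0.17, adjusted p = 0.00232) and 1 fell, the sulfiredoxin srxn1 (-0.90). When adjusted over the list alone 5 rose and 1 fell (median 0.25, adjusted p = 6.29e-05; adjusted p = 0.83 with an estimated correlation). The glucose production genes pck1 and g6pc1a.2 rose by 1.35 and 1.29, and the hepatic glucose-phosphorylating gck fell by 1.95 (SE 0.29, adjusted p = 0.000169). These were the 3 that changed among 47 glucose metabolism genes, with the counts unchanged when adjusted over the list alone (adjusted p = 0.016; adjusted p = 0.922 with an estimated correlation). The fasting-induced pyruvate dehydrogenase kinase pdk4 rose by 1.25, the lipase lipca by 0.97, and elovl5, of fatty acid elongation, fell by 1.15, although its other 2 probes had the opposite sign. These were the 3 that changed among 53 fatty acid genes (adjusted p = 0.0311; adjusted p = 0.922 with an estimated correlation), with 2 higher and 1 lower also when adjusted over the list alone.

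**Figure D3:**
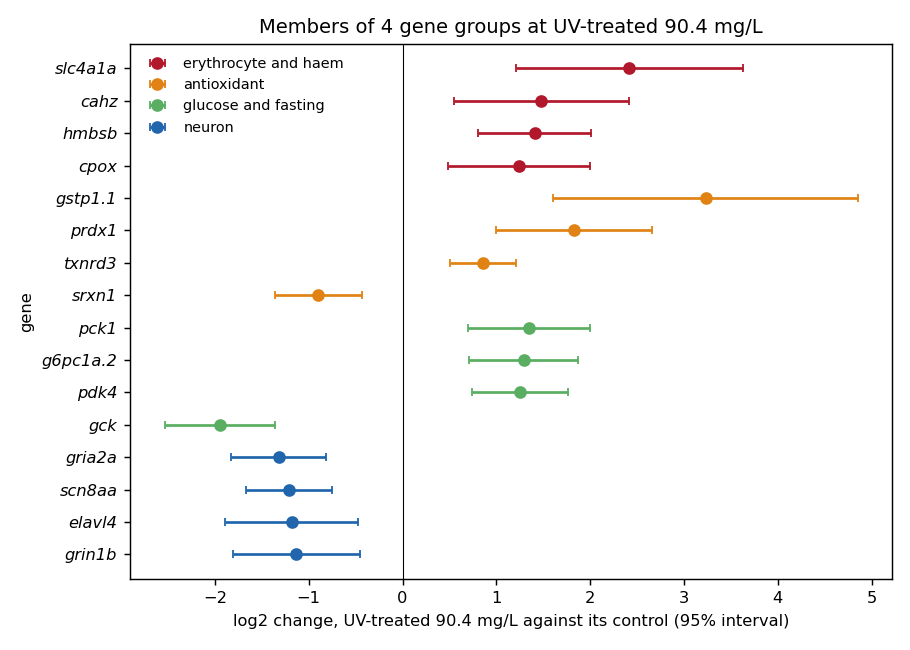
Log2 change at UV-treated 90.4 mg/L against its control (horizontal axis, points with 95% intervals) for members of 4 gene groups (vertical axis), 4 exposed against 3 control arrays. Erythrocyte and haem genes lie between 1.24 (cpox) and 2.42 (slc4a1a), and neuronal genes between -1.32 (gria2a) and -1.13 (grin1b).

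Of 56 neuronal genes 8 fell over all probes in the same larvae and 48 did not pass, with 9 lower when adjusted over the list alone. The glutamate receptor subunits gria2a (-1.32, SE 0.25, adjusted p = 0.00113) and grin1b (-1.13), the sodium channel scn8aa (-1.21, SE 0.22, adjusted p = 0.00108) and the RNA-binding protein elavl4 (-1.18, 1 of its other 2 probes with the opposite sign) were the largest. The list as a whole was not called (median -0.18, adjusted p = 0.0573; adjusted p = 0.931 with an estimated correlation). Of 35 interferon response genes 3 fell, also when adjusted over the list alone, namely the interferon ifnphi1 (-1.12), mxc (-1.11, its other 2 probes with the opposite sign) and gbp4 (-0.89), with a median of -0.49 (adjusted p = 0.0385; adjusted p = 0.922 with an estimated correlation). The clock genes bmal1b (-1.37) and cry3a (-0.86) fell, the 2 of 38 clock genes that did so, and also the 2 when adjusted over the list alone (median -0.37, adjusted p = 0.0202; adjusted p = 0.922 with an estimated correlation). Of 51 inflammation and acute phase genes crp2 and crp3 (1.75) rose and the leukocyte receptor gpr84 fell (-0.80, its other probe with the opposite sign), while 1 fell when adjusted over the list alone. The median of that list was -0.004, its mean 0.08, and it was not called (adjusted p = 0.226; adjusted p = 0.985 with an estimated correlation).

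Smaller groups at UV-treated 90.4 mg/L each held 1 or 2 changed members, and each of their calls was lost with an estimated correlation. In oxidative phosphorylation ndufa1 fell (-1.11, SE 0.17, adjusted p = 0.000185) and ndufa9a rose (0.52) among 77 genes, with a median of 0.19 and 1 falling when adjusted over the list alone (adjusted p = 0.922 with an estimated correlation). In the unfolded protein response and amino acid starvation list atf5a fell (-1.23), 1 of 45 and also 1 when adjusted over the list alone, while the list median was 0.17 (adjusted p = 0.0455; adjusted p = 0.922 with an estimated correlation). The mitochondrial chaperonin hspe1 rose (0.82), 1 of 30 heat shock genes (1 when adjusted over the list alone; adjusted p = 0.922 with an estimated correlation). In the glucocorticoid list pck1 alone rose of 29 genes (1 when adjusted over the list alone; adjusted p = 0.922 with an estimated correlation). In the intestine list apoa4a alone rose of 42 genes (1 when adjusted over the list alone; adjusted p = 0.922 with an estimated correlation). In the liver list lipca rose of 48 genes (0 when adjusted over the list alone; adjusted p = 0.982 with an estimated correlation) and in the skin and ionocyte list trpv6 rose of 55 genes (0 when adjusted over the list alone; adjusted p = 0.922 with an estimated correlation).

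The number of probes that differed at UV-treated 90.4 mg/L depended on the group it was compared with. Over all probes 82 were lower and 42 higher than in the parent control, 70 and 29 of them among the 2257 and 405. Against UV-treated 45.6 mg/L 3 were lower and 1 higher, and against UV-treated 5.5 mg/L 1998 were lower and 360 higher. Over the 2257 lower probes, which were chosen for low values at UV-treated 90.4 mg/L, the UV-treated control lay 0.59 above the parent control, parent 5.5 mg/L 0.57 above it and UV-treated 45.6 mg/L at -0.03. These comparisons with other groups were chosen after the data were seen. The count became 1593 without control replicate 2, 1073 without control replicate 3 and 1504 without exposed replicate 2. It was 9399 with array weights, 4565 with the compared groups fitted alone and 1631 with normexp. With the slide as a fixed block 2944 probes were called (493 higher, 2451 lower), 2311 of them shared with the 2662. Within slide 3, with 1 exposed and 2 control arrays, the medians were 1.07 and -1.33 for the probes called higher and lower. The list medians there were 1.04 for the erythrocyte, 0.34 for the antioxidant and -0.36 for the neuronal list. Quantile normalization gave 645 higher and 1599 lower probes. With the slide as a fixed block the calls of the liver, fatty acid and interferon lists were lost.

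**Figure D4:**
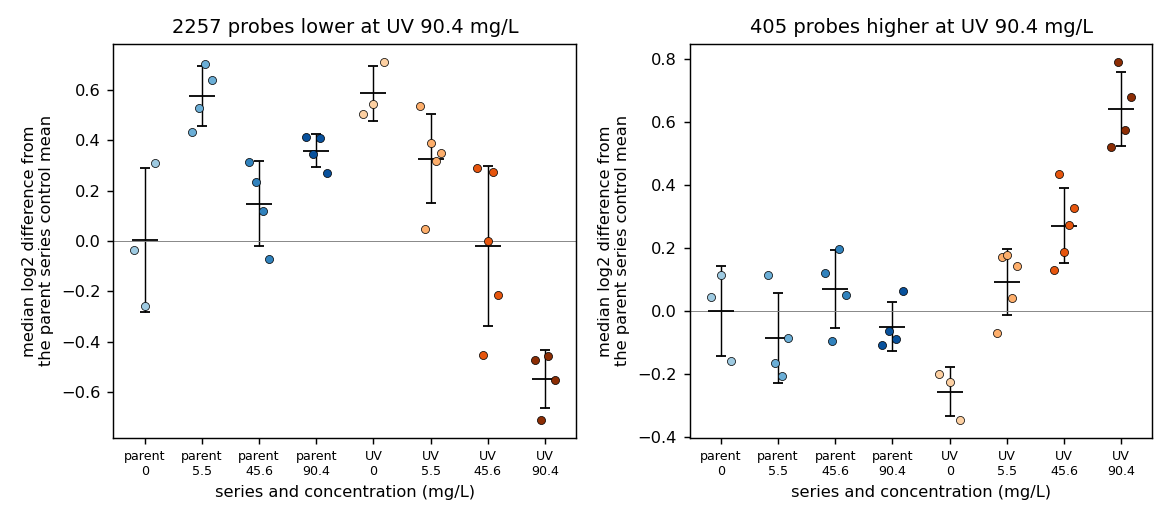
Median log2 difference from the parent control mean (vertical axes) over the 2257 probes lower (left) and the 405 probes higher (right) at UV-treated 90.4 mg/L, in each array by series and concentration in mg/L (horizontal axes), with a point per array and bars for the group mean and SD. The group medians of the lower probes were -0.57 at UV-treated 90.4 mg/L and 0.59 in the UV-treated control. The probes were chosen by the comparison of these groups.

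The effect of exposure differed between the forms at each concentration. At 5.5 mg/L, the glucocorticoid-responsive genes fkbp5 (log2 difference of effects 4.04, SE 1.00, adjusted p = 0.0486) and klf9 (3.96, adjusted p = 0.0337) were higher in the UV-treated effect. So were the clock genes nfil3-5 (2.68, SE 0.39, adjusted p = 0.00226) and rorcb (2.47, adjusted p = 0.0131) and the hormone gene gh1 (adjusted p = 0.0255), whose size is not given because 3 of its 4 groups had no array above background. Lower were lmbr1l (-7.35), apob (-4.14), spire2 (adjusted p = 0.0422, its parent control not above background), znfl1 (-3.18) and the calcium-binding cabp5a (-2.61). Also lower were the clock output gene dbpa (-1.95), cry5 (-1.81), the cone genes pde6c (-1.48) and arr3a (-1.19) and the DNA repair gene xpc (-1.43). Of 38 clock genes 4 were higher and 5 lower, and 8 and 12 when adjusted over the list alone (median -0.35, adjusted p = 0.612; adjusted p = 0.992 with an estimated correlation). In the glucocorticoid list 3 of 29 were higher (7 when adjusted over the list alone; adjusted p = 0.922 with an estimated correlation). In phototransduction 2 of 52 were lower (7 when adjusted over the list alone; adjusted p = 0.922 with an estimated correlation). In the p53 and DNA damage list xpc was the 1 of 33 that was lower although the list median was 0.52 (1 lower when adjusted over the list alone; adjusted p = 0.922 with an estimated correlation). In all 280 probes differed (54 higher, 226 lower). That count was 77, 48 or 26 without UV-treated control replicates 1, 2 or 3, and 25, 21 or 804 without parent control replicates 1, 2 or 3. It was 135, 44 or 58 without parent 5.5 mg/L replicates 2, 3 or 4, and 104, 119 or 127 without UV-treated 5.5 mg/L replicates 2, 4 or 5. It was 300 with the slide as a fixed block. Of the 15 named genes 1 kept its call without any 1 array and 0 kept it in every other alternative. The call of fkbp5 was lost in 19 of 33 alternatives, cry5 in 18 of 34, and pde6c, arr3a and xpc in 17 of 34 each. That of nfil3-5 was lost in 1 of 34 and that of rorcb in 2 of 33. The UV-treated effect of fkbp5 by itself was 0.29 (adjusted p = 0.982).

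At 45.6 mg/L the interferon response of the parent form was not matched by the UV-treated form. The difference of effects was -5.42 for isg15 (adjusted p = 0.00151). It was also negative for mxb (adjusted p = 0.00245), ifit8 (adjusted p = 0.00135) and the antiviral enzyme rsad2 (adjusted p = 1.88e-05). Their sizes are not given, because mxb and ifit8 were above background on 0 of 3 parent control arrays, and rsad2 on none in either control or at UV-treated 45.6 mg/L. Of 35 interferon genes 14 were lower (21 when adjusted over the list alone), with a median of -1.36 (adjusted p = 1.11e-25; adjusted p = 0.000674 with an estimated correlation). Markers of myeloid and lymphoid cells went the same way, with 0 of 43 passing. Their mean log2 difference from their mean over all arrays was -0.033 to 0.587 on the parent 45.6 mg/L arrays. On the UV-treated 45.6 mg/L arrays it was -0.549 to 0.064. The immediate-early gene egr2a (2.59) and rt (2.44) were higher and lmbr1l (-7.25) was lower. In all 187 probes differed (6 higher, 181 lower). The count was 98, 97 or 108 without UV-treated control replicates 1, 2 or 3, 95, 116 or 380 without parent control replicates 1, 2 or 3, 105 without parent 45.6 mg/L replicate 1, and 293 or 311 without UV-treated 45.6 mg/L replicates 1 or 4. The slide as a fixed block gave 155 probes, and the compared groups fitted alone gave 18.

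At 90.4 mg/L the bile acid-induced genes fgf19 (log2 difference of effects 4.90, SE 1.40, adjusted p = 0.0332) and nr0b2b (4.29), cyp2k22 (4.79), snu13a (3.95, its other probe with the opposite sign) and slc22a6l (3.39, SE 0.43, adjusted p = 4.21e-05) were higher in the UV-treated effect. So were slc4a1a (3.22), crp2 (3.18), rfesd (3.14), rt (2.66), tbc1d7 (2.16), prdx1 (adjusted p = 0.0248) and the calcium-regulated carrier slc25a25a (1.97). Lower were lmbr1l (-7.68), dmrt1 (-3.98) and bcl11ba (-3.34, SE 0.47, adjusted p = 7.5e-05). So were the receptor kinase erbb4a (-3.28), the sodium channel scn5lab (-3.24) and inpp4aa (-3.03, SE 0.38, adjusted p = 4.21e-05). Also lower, with sizes not given because the parent control and in part other groups had no array above background, were the ventralizing homeobox gene vox (adjusted p = 0.00151), magi2a (0.00171), kcnq3 (0.000281), sox32 (0.0016), spire2 (0.0289) and ftr03 (0.00208). Of 34 erythrocyte and haem genes 6 were higher, among them hmbsb (1.81), urod (1.29) and the embryonic globin hbae3 (1.26), and 8 when adjusted over the list alone (median 0.88; adjusted p = 0.83 with an estimated correlation). Of 56 neuronal genes 7 were lower, among them elavl4 (-1.99), gria2a (-1.46), the GABA-synthesizing gad2 (-1.30) and scn8aa (-1.29), and 10 when adjusted over the list alone (adjusted p = 0.922 with an estimated correlation). Of 26 cholesterol synthesis genes idi1 (1.94) was higher, with a list median of 0.87 and 3 higher when adjusted over the list alone (adjusted p = 0.000202; adjusted p = 0.922 with an estimated correlation). Of 45 antioxidant genes prdx1, gpx1b (1.37) and txnrd3 (0.81) were higher, 4 when adjusted over the list alone (adjusted p = 0.922 with an estimated correlation). The urea cycle gene ass1 was the 1 of 24 arginine genes that was higher (1.65, its other 2 probes with the opposite sign; 0 when adjusted over the list alone; adjusted p = 0.922 with an estimated correlation). The arginine call was also lost with the slide as a fixed block. In oxidative phosphorylation uqcrfs1 (0.88) and ndufb2 (0.71, its other probe with the opposite sign) were higher and ndufa1 lower (-1.84, SE 0.24, adjusted p = 4.21e-05) among 77 genes, with 1 lower when adjusted over the list alone and a list median of 0.25 (adjusted p = 0.922 with an estimated correlation). The heat shock gene hspe1 was higher (1.09), 1 of 30 and also 1 when adjusted over the list alone (adjusted p = 0.922 with an estimated correlation). In the inflammation list crp2 was higher and gpr84 lower (-1.16, its other probe with the opposite sign) among 51 genes, 4 and 1 when adjusted over the list alone (adjusted p = 0.922 with an estimated correlation).

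In all 2031 probes differed between the forms at 90.4 mg/L, 232 higher and 1799 lower. By gene, 1351 of 20558 differed, 148 higher and 1203 lower. The cholesterol, arginine, oxidative phosphorylation, heat shock and inflammation lists had a smaller share called than all genes, and the antioxidant list about the same. The count was 1170 without parent control replicate 2 and 1268 without UV-treated control replicate 3, and 2053 with the slide as a fixed block. Normexp moved the median difference of all probes to -0.14, with 154 higher and 1304 lower probes, and leaving dim probes unfiltered moved it to -0.15. Of 40 named genes 17 kept their call without any 1 of the arrays, slc22a6l, snu13a, bcl11ba, inpp4aa and hmbsb among them. Only 13 of the 40 kept it in every other alternative as well. The call of ass1 was lost in 20 of 33 alternatives, uqcrfs1 in 19 of 33, ndufb2 in 18 of 33 and txnrd3 in 16 of 33. Those of fgf19 and nr0b2b were lost in 10 and 9 of 32, with log2 differences down to 2.481 and 1.187. Across all probes, effects of the parent and UV-treated forms had Pearson correlations of -0.265 at 5.5, 0.003 at 45.6 and -0.171 at 90.4 mg/L (0.014 in simulated unchanged groups at 90.4), and probes are not independent replicates. At 90.4 mg/L 2 probes were lower in both forms (0.13 expected of independent lists), with 8 called in opposite directions. Within the UV-treated series the effects at 45.6 and 90.4 mg/L correlated at 0.734, against 0.594 in simulated unchanged groups with the same controls. The covariance was 0.189, against 0.0776 in the simulation. These simulations drew each probe independently, without variation shared within an array, so they are not a full baseline.

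Averaged over the 4 concentrations, including 0 mg/L, the series differed most in the circadian clock. Of 38 clock genes 21 differed, 7 higher and 14 lower in the UV-treated series, and 30 when adjusted over the list alone. The 21 were 55.3% of the list, against 2.7% of all genes (Fisher's exact test, one-sided, adjusted p = 1.98e-21). Here and for the lists that follow, this test allows for no correlation between the genes of a list, so its p-values can be too small. Called genes of the activator phase were higher, rorcb by 1.58 (SE 0.15, adjusted p = 1.95e-07), nfil3-5 by 1.57 (SE 0.13, adjusted p = 2.47e-08), bmal1a by 0.82 and, near background in most groups, clocka (adjusted p = 8.55e-05). Called genes of the repressor phase were lower, among them dbpa (-1.24), per1b (-1.16) and nr1d2b (-0.71). The gene cry5 of the clock list, placed in neither phase, was also lower (-1.45, SE 0.15, adjusted p = 7.03e-07). Between the control groups alone 0 of the 38 clock genes passed, also when adjusted over the list alone. With 3 arrays in each control group this does not show that their clock genes were at equal levels. In bmal1a the mean log2 level was 1.57 (SD 0.11, n = 3) in the parent control and 1.80 (SD 0.06, n = 3) in the UV-treated control, then 0.91 (SD 0.11, n = 4) and 2.42 (SD 0.08, n = 5) at 5.5 mg/L.

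**Figure D5:**
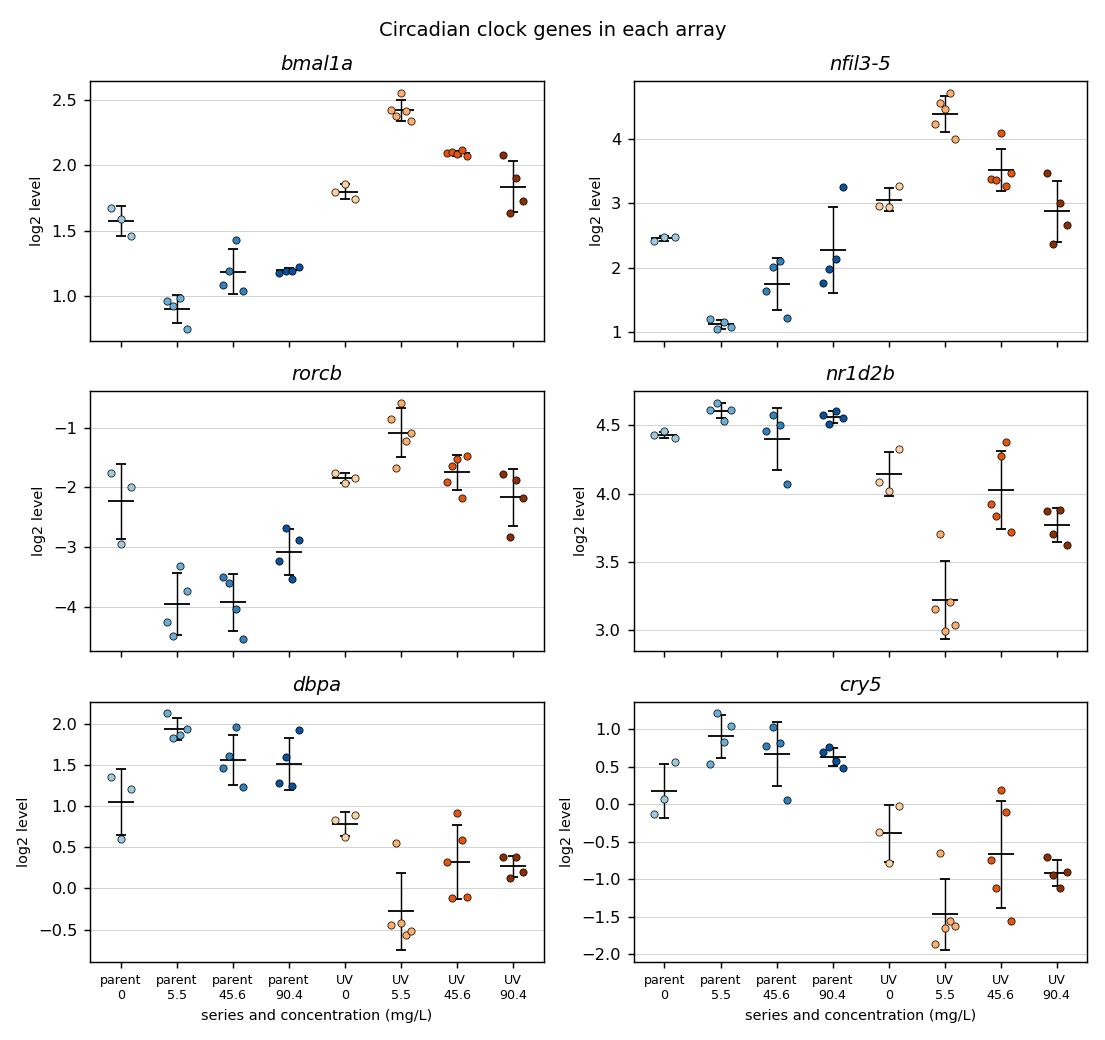
Normalized log2 level (vertical axes) of bmal1a, nfil3-5, rorcb, nr1d2b, dbpa and cry5, members of the clock list, in each array by series and concentration in mg/L (horizontal axis), with a point per array and bars for the group mean and SD. At 5.5 mg/L bmal1a had a mean of 0.91 (SD 0.11) in the parent series and 2.42 (SD 0.08) in the UV-treated series.

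Phototransduction genes also differed between the series, 12 of 52 (3 higher, 9 lower; 24 when adjusted over the list alone; Fisher's exact test, adjusted p = 3.27e-07). The red cone opsin opn1lw2 was higher (1.49, SE 0.26) and the cone arrestins arr3b (-1.12) and arr3a (-0.83, adjusted p = 3.79e-06) and the opsin kinase grk7a (-0.90) were lower. All 7 changed genes of the glucocorticoid and stress axis were higher in the UV-treated series, among them fkbp5 (1.82, SE 0.34, adjusted p = 0.00254), klf9 (1.19), the cortisol-inactivating hsd11b2 (1.00, adjusted p = 5.3e-05) and pck1 (0.70), out of 29 measured (15 when adjusted over the list alone; adjusted p = 0.000194). The glucocorticoid list stood low on the 4 parent 5.5 mg/L arrays, at levels of -0.764 to -0.449, and 3 of these arrays lay on slide 2. For fkbp5 the difference of effects was 4.04 at 5.5 mg/L. It was 1.21 at 45.6 mg/L (limma, adjusted p = 0.82) and 1.41 at 90.4 mg/L (adjusted p = 0.505). On 2 UV-treated arrays this list stood high, with a level of 0.83 in 5.5 mg/L replicate 2 (others of the group -0.109 to 0.253) and 0.892 in 45.6 mg/L replicate 3 (others 0.097 to 0.605). Without both arrays 5 of the 7 genes kept the call, klf9 not among them (adjusted p = 0.0538), and the phototransduction list had 11 higher and 8 lower. Also higher were 6 of 40 hypoxia genes, ddit4 (1.23), ndrg1b (1.11), pfkfb4b (0.86) and pfkfb3 (0.72) leading (7 when adjusted over the list alone; adjusted p = 0.0117). The lists of p53 and DNA damage (ddb2 -0.76, xpc -0.74, tp53inp1 0.77; adjusted p = 0.714), intestine (alpi.2 -1.08, pigrl2.3 -0.92, slc5a1 -0.58; adjusted p = 0.978) and interferon response (b2m -0.70, pkz -0.63 and, above background in 1 of 8 groups, rsad2 lower; adjusted p = 0.748) had 3 changed members each. When adjusted over the list alone they had 8, 7 and 5, and they did not pass the enrichment test. For alpi.2 the controls also lay apart, at 1.74 (SD 0.45) in the parent and 0.91 (SD 0.19) in the UV-treated control. For pigrl2.3 they were close, at -3.90 and -3.88. In all 913 probes differed (444 higher, 469 lower), 747 with the slide as a fixed block and 142 without slide 2. Normexp gave 281 higher and 646 lower.

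The difference between the forms depended on concentration for 1775 probes in the F test of the interaction. Interferon response genes made up 18 of 35 (25 when adjusted over the list alone; Fisher's exact test, adjusted p = 3.74e-12) and clock genes 11 of 38 (19 when adjusted over the list alone; adjusted p = 0.000169). Of the lists that did not pass, neuronal genes made up 6 of 56 (10 when adjusted over the list alone; adjusted p = 0.978), myeloid and lymphoid markers 6 of 43 (10 when adjusted over the list alone; adjusted p = 0.497) and glucose metabolism 5 of 47 (5 when adjusted over the list alone; adjusted p = 1). The p53, erythrocyte, phototransduction, glucocorticoid, fatty acid and oxidative phosphorylation lists had 3 each and 3, 5, 10, 3, 3 and 1 when adjusted over the list alone (adjusted p = 1 for each). The count was 1150 without parent control replicate 2, 1101 without UV-treated control replicate 3 and 1731 with the slide as a fixed block.

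Interferon genes differed between concentrations averaged over both forms, 15 of 35 in the F test (25 when adjusted over the list alone; Fisher's exact test, adjusted p = 1.11e-13), among 784 probes. This average does not show a rise in both forms. The mean log2 difference of the list from its mean over all arrays was 1.181 to 2.147 on the parent 45.6 mg/L arrays. On the UV-treated 45.6 mg/L arrays it was -0.335 to 0.2. Neuronal genes (3 of 56, 4 when adjusted over the list alone; adjusted p = 1) and glucocorticoid genes (3 of 29, 3 when adjusted over the list alone; adjusted p = 0.497) did not pass the enrichment test. The count of 784 probes became 502, 387 or 406 without parent 5.5 mg/L replicates 2, 3 or 4. It became 453, 1798, 507 or 502 without UV-treated 5.5 mg/L replicates 1, 2, 3 or 5. It was 1267 without UV-treated 45.6 mg/L replicate 1, 433 without UV-treated 90.4 mg/L replicate 2 and 594 with the slide as a fixed block. Camera called 83 of 270 pairs of a list and a comparison with its preset correlation and 2 with an estimated correlation, both of the interferon list (parent 45.6 mg/L and the difference at 45.6 mg/L).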

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

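The tests weighing 3 patterns were chosen after the results were seen, and the counts over other splits of the arrays followed a rule set beforehand but were written down after being seen.

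Single arrays stood apart from the others of their group in 24 of 218 groups of values tested, where chance alone marks about 1 in 20 groups, or 10.9. By signal level, the 75th percentile of parent 90.4 mg/L replicate 1 was 597 (others 292.2 to 343.4) and that of UV-treated 90.4 mg/L replicate 2 was 606.9 (others 512.9 to 527.8). In UV-treated 90.4 mg/L replicate 4, 68.68% of probes were well above background (others 79.26 to 80.1). The median CV of repeated spots was 28.75% in parent 45.6 mg/L replicate 3 (others 6.14 to 7.48), 18.59% in UV-treated 45.6 mg/L replicate 4 (others 6.12 to 7.57) and 13.44% in UV-treated 90.4 mg/L replicate 1 (others 5.8 to 6.55).

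UV-treated 45.6 mg/L replicate 3 was far from its group in several gene groups. Its list level, the mean log2 difference of the genes of a list from their mean over all arrays, was -0.395 for oxidative phosphorylation (others -0.059 to 0.065), 0.77 for inflammation (others -0.078 to 0.12), 0.494 for p53 and DNA damage (others -0.034 to 0.043) and -0.489 for arginine and urea (others -0.048 to 0.115). Larger distances lay in other lists, which were set beforehand but picked for this description after the values were seen. They were -1.743 for extracellular matrix (others -0.357 to 0.383), -1.289 for liver (others -0.441 to 0.643) and -1.234 for skeletal muscle (others -0.338 to 0.247). For intestine the level was -1.116 (others -0.243 to 0.309) and for proliferation -1.026 (others -0.367 to 0.195). UV-treated 5.5 mg/L replicate 2 went the same way, with -0.942 for matrix (others -0.187 to 0.512), -0.929 for intestine (others -0.33 to 0.081) and 0.83 for the glucocorticoid axis (others -0.109 to 0.253). These arrays lay at 116.6 and 91.7 on principal component 1. UV-treated 45.6 mg/L replicate 5 had an erythrocyte level of 1.02 (others -0.149 to 0.055). In the parent series, oxidative phosphorylation was 0.121 in 5.5 mg/L replicate 2 (others -0.02 to -0.004), liver genes 0.216 in 45.6 mg/L replicate 4 (others -0.256 to -0.19) and fatty acid genes 0.155 in 90.4 mg/L replicate 3 (others -0.107 to -0.063). The unfolded protein response was 0.497 in UV-treated 5.5 mg/L replicate 2 (others -0.201 to -0.057), and arginine genes were 0.239 in UV-treated 90.4 mg/L replicate 3 (others 0.007 to 0.035).

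Among named genes, the log2 level of fkbp5 was -6.386 in parent 5.5 mg/L replicate 2 (others -4.211 to -3.89) and that of ifit8 -3.498 in parent 45.6 mg/L replicate 4 (others -0.798 to -0.587). Parent 90.4 mg/L replicate 4 stood apart for inpp4aa at 0.034 (others -0.927 to -0.846) and aep1 at 3.747 (others 2.582 to 2.775). In the UV-treated series gpr55a was -4.364 in 5.5 mg/L replicate 1 (others -3.376 to -3.245) and slc22a6l was -0.51 in 45.6 mg/L replicate 1 (others 0.179 to 0.39). In UV-treated 90.4 mg/L replicate 1, bmal1b was -0.849 (others -1.786 to -1.654) and gbp4 was -1.188 (others -0.92 to -0.889).

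The effects of the forms differed by a test of the difference for 280 probes at 5.5 mg/L, 187 at 45.6 mg/L and 2031 at 90.4 mg/L. The interaction gave 1775 probes, and the interferon list at 45.6 mg/L had a median log2 difference of -1.364.

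Genes that fell at UV-treated 90.4 mg/L were the most numerous pattern. A difference between slides was tested by adding the slide as a fixed block, which kept 2311 of the 2662 calls and speaks against the slide as the cause. The level of the UV-treated control as the whole cause was weighed in tests of all probes with no control in them. Against the mean of the other 2 UV-treated exposed groups 1284 were lower, 1062 of them among the 2257. The same 90.4 mg/L arrays chose the 2257, which may raise that shared count. Alone, UV-treated 5.5 mg/L gave 1998 lower (1446 shared) and UV-treated 45.6 mg/L gave 3. These values argue against the control as the whole cause for the difference from UV-treated 5.5 mg/L. For UV-treated 45.6 mg/L they do not. As a part of the change, the level of the control cannot be told apart from a response, since only 70 of the 2257 were called lower against the parent control in a test of all probes. Signal near background as the whole cause is argued against by 39.6% of the lower probes lying above the median brightness of the tested probes. For the dimmer probes it cannot be told apart from a change of transcripts, since the median change of all probes was -0.242 and -0.174 in the 2 dimmest of 5 brightness groups and 0.036 and 0.033 in the 2 brightest. A response to the UV-treated stock also stays open.

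Interferon genes were higher at parent 45.6 mg/L. With the slide as a fixed block 127 of the 136 calls were kept, which speaks against the slide. More immune cells in the extracts are argued against by the upper quartile of the myeloid and lymphoid list, 0.572, lying below the interferon list's median of 1.328. A response that grows with parent concentration is argued against by 17 of 35 interferon genes being lower at 90.4 than at 45.6 mg/L, with 0 higher. An infection in these beakers could give such a rise, as could a response at that concentration alone, and neither was tested.

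Clock genes differed between the forms. With the slide as a fixed block all 21 called clock genes were kept, which speaks against the slide. Another clock phase of the larvae at sampling may account for it: the 12 called genes of both phases lay on opposite sides, 5 activator-phase genes higher and 7 repressor-phase genes lower. Between the controls 0 clock genes passed, which with so few control arrays does not show that their phases were equal. Phase and exposure cannot be told apart for these genes, since the labels give no sampling time.

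Other splits of the same arrays were counted for each result. The real split gave the most probes for parent 5.5 mg/L (302 probes, 1 of 35 splits as large, highest other 2) and 45.6 mg/L (136, 1 of 35, highest other 98). The same was seen for parent 90.4 mg/L (11, 1 of 35, highest other 5) and UV-treated 90.4 mg/L (2662, 1 of 35, highest other 350). A share of 1 of 35 is the lowest these splits can give. No correction was made over the results, so the splits alone do not exclude chance. The real count was also the largest for the differences at 5.5 mg/L (280, 1 of 100, highest other 0), 45.6 mg/L (187, 1 of 100, highest other 4) and 90.4 mg/L (2031, 1 of 100, highest other 0). So it was for the interaction (1775, 1 of 100, highest other 140) and concentration (784, 1 of 100, highest other 96). For form (913) 3 of 100 splits were as large, the real one among them, and the highest other was 3119. The count for form thus lay within the spread of the other splits, and chance is not excluded for it. Chance cannot be excluded for UV-treated 5.5 mg/L (3 probes, 3 of 56, highest other 6), UV-treated 45.6 mg/L (6, 4 of 56, highest other 839) or the list tests (83 calls, 56 of 100, highest other 141). The splits do not keep the slides: 3 of the 4 parent 5.5 mg/L arrays lay on slide 2, which held no control. With the slide as a fixed block the counts were 12 at parent 5.5 mg/L and 0 at parent 90.4 mg/L, so the splits do not exclude the slide there. The splits with 839 and 3119 probes point to a structure of the arrays beside the groups. For control against control the 10 splits are too few, with 0 probes in the real split and 0 as the highest other, all 10 as large.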

How the results depend on the processing

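Leaving out the 3 arrays with a median CV above 20%, the 2 arrays at the end of principal component 1 or slide 2, and the CV covariate, were chosen after the data were seen. Of 3058 values of named genes under 19 alternatives other than leaving out an array, 2677 kept their direction and side of the threshold, 357 were weaker, 24 stronger and 0 reversed. Of 2302 values with an array left out, 1809 were kept, 482 were weaker, 11 stronger and 0 reversed. For lists, 466 of 561 values were kept, 88 were weaker, 6 stronger and 1 reversed, and with an array left out 1009 of 1056 were kept. The reversed value was the circadian clock list in the difference at 5.5 mg/L with the deposited series values (median -0.127, adjusted p = 0.963), where the direction of the list test changed and no call was made, as in the reported fit. The adjusted p of that list reached 0.992 over its 49 alternatives. The interferon list kept its call in all 49 alternatives at parent 45.6 mg/L (medians 0.865 to 1.654) and in the difference at 45.6 mg/L (medians -1.803 to -1.116). Where the counts below moved, the cause was not tested, except that a threshold of 0.1 admits more probes and fewer arrays or probes were tested where some were left out.

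With an adjusted p under 0.1 the probes numbered 566 at parent 5.5 mg/L, 20 at parent 90.4 mg/L, 12 at UV-treated 5.5 mg/L, 91 at UV-treated 45.6 mg/L and 4120 at UV-treated 90.4 mg/L. They were 878 and 356 for the differences at 5.5 and 45.6 mg/L, 2985 for the interaction, 1665 for form, 1629 for concentration and 1 for the controls. A change of at least 1.5-fold left 470 for form.

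Normexp gave 98 at parent 5.5 mg/L, 0 at parent 90.4 mg/L (limma, 3009 at an unadjusted p under 0.05 as reported), 0 at UV-treated 5.5 mg/L (2079 likewise), 13 at UV-treated 45.6 mg/L, 1631 at UV-treated 90.4 mg/L, 100 for the difference at 5.5 mg/L and 375 for concentration. It moved the median of all probes at parent 90.4 mg/L to 0.10. Quantile normalization gave 1 at UV-treated 5.5 mg/L. No filter gave 154 at parent 5.5 mg/L, 6 at parent 90.4 mg/L, 0 at UV-treated 5.5 mg/L and 150 for the difference at 5.5 mg/L, and moved the median of all probes at UV-treated 90.4 mg/L to -0.12. A filter on all 32 arrays gave 73 at parent 45.6 mg/L, 7 at parent 90.4 mg/L, 0 at UV-treated 5.5 mg/L, 2 at UV-treated 45.6 mg/L, 117 for the difference at 45.6 mg/L and 1 for the controls. Signal over background limited the sizes that could be given: where a group had no array above it, as for mxb or vox, a change is given as a bound or without a size.

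The slide as a fixed block gave 12 at parent 5.5 mg/L, 0 at parent 90.4 mg/L, 0 at UV-treated 5.5 mg/L and 16 at UV-treated 45.6 mg/L. Without slide 2 the counts were 0 at parent 5.5 mg/L, parent 90.4 mg/L, UV-treated 5.5 mg/L and UV-treated 45.6 mg/L (5057, 3009, 2079 and 3926 at an unadjusted p under 0.05 as reported by limma), 0 and 75 for the differences at 5.5 and 45.6 mg/L, 519 for the interaction, 142 for form and 53 for concentration. That fit held 1 parent 5.5 mg/L array, assumed to vary like the other groups, so that its 0 at parent 5.5 mg/L and for the difference there say little. The array row as a covariate gave 182 at parent 5.5 mg/L, 6 at parent 90.4 mg/L and 0 at UV-treated 5.5 mg/L. A block on the replicate number, which does not pair the samples by the correlations of same-numbered arrays (7 of 18 above 0.1), gave 0 at UV-treated 5.5 mg/L and 12 for the controls.

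Array weights gave 1402 at parent 5.5 mg/L, 9399, 1385 and 180 at UV-treated 90.4, 45.6 and 5.5 mg/L, 4323, 636 and 2138 for the differences in that order, 5178 for the interaction, 2389 for form, 3839 for concentration and 313 for the controls. Pooled controls gave 23 at parent 5.5 mg/L, 2 at parent 90.4 mg/L, 47 at UV-treated 5.5 mg/L, 26 at UV-treated 45.6 mg/L, 1328 and 416 for the differences at 5.5 and 45.6 mg/L and 456 for concentration. A direct difference of the exposed groups gave 1319 at 5.5 mg/L and 403 at 45.6 mg/L. With the compared groups fitted alone there were 0, 69 and 1 at parent 90.4, 45.6 and 5.5 mg/L, 0 at UV-treated 5.5 mg/L, 4565 at UV-treated 90.4 mg/L, 18 for the difference at 45.6 mg/L and 1 for the controls. The estimated correlation left 2 list calls.

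Without the 3 arrays of high CV there were 176 at parent 5.5 mg/L, 0 at parent 90.4 mg/L, 7 at UV-treated 5.5 mg/L, 463 for the difference at 5.5 mg/L and 470 for concentration. Without the 2 arrays at the end of principal component 1 there were 682 at parent 5.5 mg/L, 7 at parent 90.4 mg/L, 12 at UV-treated 5.5 mg/L, 12 at UV-treated 45.6 mg/L, 142 for the difference at 5.5 mg/L and 1740 for concentration. The CV covariate gave 0 at parent 90.4 mg/L and 1 at UV-treated 5.5 mg/L.

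With each array left out in turn the counts ranged from 0 (without control replicate 2) to 641 (without control replicate 3) at parent 5.5 mg/L, 104 to 147 at parent 45.6 mg/L and 0 to 106 (without control replicate 3) at parent 90.4 mg/L. In the UV-treated series they ranged from 0 to 11 (without exposed replicate 2) at 5.5 mg/L, 0 (without exposed replicate 3) to 245 (without exposed replicate 1) at 45.6 mg/L and 1073 (without control replicate 3) to 2622 at 90.4 mg/L. The differences ranged from 21 to 804 (without parent control replicates 2 and 3) at 5.5 mg/L, 95 to 380 (without parent control replicates 1 and 3) at 45.6 mg/L and 1170 (without parent control replicate 2) to 2450 at 90.4 mg/L. The interaction ranged from 1101 (without UV-treated control replicate 3) to 2206, form from 615 to 1198, concentration from 387 (without parent 5.5 mg/L replicate 3) to 1798 (without UV-treated 5.5 mg/L replicate 2), the controls from 0 to 232 (without parent control replicate 3) and the list calls from 74 to 94.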

Other observations

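The lists and gene below were described after their values were seen, and no test of an explanation was made for them. Cell proliferation genes moved most widely among the lists not described so far, with medians between -0.354 and 0.64 over the effects of exposure and their differences between the forms, and 0 of 61 measured genes passed in these (limma). Extracellular matrix, cartilage and bone genes ranged from -0.391 to 0.462 (0 of 51) and markers of myeloid and lymphoid cells from -0.526 to 0.323 (0 of 43). Ribosomal protein genes ranged from -0.191 to 0.206 (0 of 78) and genes of xenobiotic metabolism and the aryl hydrocarbon receptor from -0.272 to 0.157 (0 of 33). In the averaged effect of form 1 proliferation gene and 1 xenobiotic metabolism gene were lower, and in the interaction 6 of 43 myeloid and lymphoid markers were called. At UV-treated 90.4 mg/L 2 of 47 lens genes and 2 of 33 exocrine pancreas genes fell, with medians over the comparisons from -0.231 to 0.145 and from -0.223 to 0.063. There 1 of 69 skeletal muscle genes rose (medians -0.278 to 0.154), and 1 of 25 genes of metal and iron handling (-0.103 to 0.328) and 1 of 29 genes of glia and myelin (-0.227 to 0.145) fell. With an estimated correlation the lowest adjusted p of these lists was 0.922, or 0.982 for the matrix and muscle lists.

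The lmbr1l probe was high in the UV-treated control and low in the parent control, and its mean log2 level went the opposite way with exposure in each series. In the parent series it was -5.68, -1.20, -2.57 and -2.62 from 0 to 90.4 mg/L, and in the UV-treated series -1.55, -4.42, -5.70 and -6.17. It was measured by a single probe. Its sizes varied widely over the alternatives, for the difference of effects at 90.4 mg/L from -8.499 to -3.046.

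Within groups the arrays correlated from 0.9348 to 0.9859. The first 3 principal components held 16.8%, 13.5% and 7.1% of the variance.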
